A study of Mus musculus with 2 samples.

How the data were processed

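Total RNA of splenic APCs from 10-week-old female C57BL/6 mice was purified with an RNeasy column, per the labels' protocols. Biotin-labelled cRNA was made from 1 µg of it with the Affymetrix One-Cycle reagents. Each condition, P25 or medium, was hybridised to 1 array, and each RNA was a mixture of 3 independent experiments, per the series' design text. The deposited values are MAS5 signal intensities made with GCOS, per the submitters' processing notes, and no versions are given there. They are on a linear scale and were never negative. MAS5 reduces the perfect-match and mismatch probes of a probe set to 1 signal and scales each array to a target. The target, the detection calls and the masks are not given in the sources used here. The 2% trimmed means over the probe sets other than controls were 124.7 (P25) and 117.5 (medium), so the arrays were not on one trimmed mean over these probe sets. The 18 hybridization spike-in probe sets had a median log2 ratio of P25 over medium of -0.15 (SD 0.10 between probe sets, from -0.45 to -0.03). MAS5 subtracts mismatch signal, so ratios of dim probe sets are noisy, and a scaling difference would shift all ratios together.

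Each array gave 45101 probe sets, of which 64 are controls. The median signals of the other 45037 were 18.0 (P25) and 18.4 (medium), and their 95th percentiles 875 and 785. Across the 29549 measured probe sets, log2 signals of both arrays correlated with Pearson's r of 0.89 and Spearman's rho of 0.93. These correlations are across probe sets, which are not independent replicates. The number of arrays, 1 per condition, limits the precision. No slide or scan date was used here, so a batch difference and the treatment cannot be told apart.

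Groups were taken from the treatment label of each sample. Before the data were examined, the ratio, the floor, the gene lists, the rule for named genes and the alternatives were fixed. The floor was the 40th percentile of the signal over both arrays without controls (10.3). Signals below it were set to it, and a ratio with 1 array at the floor is a lower bound, written "at least". A probe set was measured when at least 1 array was above the floor (60.3% of probe sets on the P25 array and 59.7% on the medium array were above it). Probe sets were named from the platform annotation, with symbols updated by Entrez number through a RefSeq gene table of the GRCm38.p6 assembly. Of the probe sets, 34945 had 1 gene symbol (204 of them without a match in the RefSeq table), 932 had several and 9160 had none, and only those with 1 were used. A gene was represented by its probe set of highest mean log2 signal, which gave 18194 genes, 12897 of them measured (70.9%) and 10917 above the floor on both arrays. Coordinates were not used here. Signals of different probe sets were not set against each other.

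A gene was counted when its ratio was at least 2 or at most 0.5. No p-value was computed, since 1 array per condition leaves no spread to test against. Disagreement between probe sets of a gene stood in for technical spread. The brightest pair of probe sets above the floor on both arrays was compared in 5293 genes, and their log2 ratios differed with an SD of 0.58, which was 0.68 where the second had a signal under 100 and 0.46 where it had 100 or more. For each of 33 gene lists the median log2 ratio of measured members was given its percentile among 10000 random lists of equal size, drawn to match mean log2 signal in 20 bins. The percentile describes these 2 arrays and is no test. Of 515 listed symbols 451 were on the array under a single name, and genes of the lists without such a probe set are not reported here. Some genes (26) belong to more than 1 list. Of 32 lists with 3 or more measured genes, 11 had a percentile above 97.5 and 4 below 2.5. If list members were as independent as randomly drawn genes, 1.6 lists outside that range would be met. Genes of one list may move together, so 1.6 is no chance expectation for these lists. Another 6 lists were chosen after the data were seen and appear only with the closing observations.

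The named genes are the 12 largest ratios in each direction among genes above the floor on both arrays, the 6 brightest genes above it on 1 array only in each direction, and in each list the 2 highest and 2 lowest members, or all of 6 or fewer. Other list members are named where a sentence counts them. The rule gave 155 genes, 101 of them past 2-fold, not all of which are named. The measured probe sets of 9 of them had ratios of both signs.

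The method was tested on simulated arrays with 200 changed genes and 12432 measured genes. The changed genes were drawn from genes above the floor on both arrays, so recovery of genes at the floor on 1 array was not tested. Of genes raised 4-fold or 8-fold or lowered 4-fold 100% passed the threshold, and lowering by 8-fold was not simulated. Of genes raised by 2-fold 50% passed, which is near what a threshold equal to the change gives by itself. The simulated noise was the disagreement between probe sets of a gene, drawn independently for each probe set. By this noise alone 105 of the unchanged genes passed 2-fold higher and 108 lower. Of 100 unchanged lists 3 fell outside percentiles 2.5 to 97.5. Differences between cultures or hybridisations, and lists whose genes move together, were not simulated. The counts are therefore no rate of false calls for the real arrays. Alternatives were floors at the 25th and 60th percentiles, no floor, a pseudocount, scaling to one median, quantile normalization, loess with a span of 0.3, the median over a gene's probe sets, omission of probe sets ending in _x_at or _s_at, and thresholds of 1.5-fold and 4-fold. A floor at the 75th percentile and scaling to the spike-in controls were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.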

Results

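Messenger RNA of mouse splenic antigen-presenting cells (APCs) was measured on 2 whole-genome Affymetrix arrays. APCs of 10-week-old female C57BL/6 mice were cultured overnight together with CD4+ T cells that carry the P25 T cell receptor, either with P25 or with medium alone. P25 is a peptide of a mycobacterial secreted antigen that this transgenic receptor recognises on MHC class II, so P25 is the condition in which the T cells meet their antigen. The APCs were then enriched, and RNA of 3 independent experiments was mixed for 1 array per condition. The design therefore asks how the transcripts of APCs differ after contact with T cells that do or do not find their peptide. With 1 array per condition there is no replicate spread and no p-value. All values below are ratios of the P25 array over the medium array, described and not tested. Technical disagreement was gauged from probe sets of one gene, whose log2 ratios differed with an SD of 0.58 over 5293 genes. The log2 ratios of 42 spike-in probe sets had an SD of 0.28, but they cover few transcripts and not the culture or the cells.

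Of 12897 measured genes, 1216 (9.43%) were at least 2-fold higher with P25 and 931 (7.22%) at least 2-fold lower. The larger differences were mostly on the higher side, with 176 genes at least 4-fold higher against 51 lower, and 30 at least 8-fold higher against 2 lower. The split depended on the scaling of the arrays. With both arrays brought to one median over the measured probe sets it was 1623 higher and 664 lower (71.0% of the calls higher, against 56.6% on the deposited scale). With both brought to one level of the spike-in controls it was 1611 and 638 (71.6% higher). These scalings moved the median log2 ratio of all genes from 0.02 to 0.15 and 0.16, and list medians below are set against random gene lists from the same arrays to give them relative to such shifts. Where a second probe set of the gene was above the floor on both arrays, 301 of 534 higher genes (56.4%) and 145 of 353 lower genes (41.1%) passed 2-fold in the same direction on it, against 9.79% and 7.39% of all genes with such a pair. None passed 2-fold in the opposite direction.

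**Figure D1:**
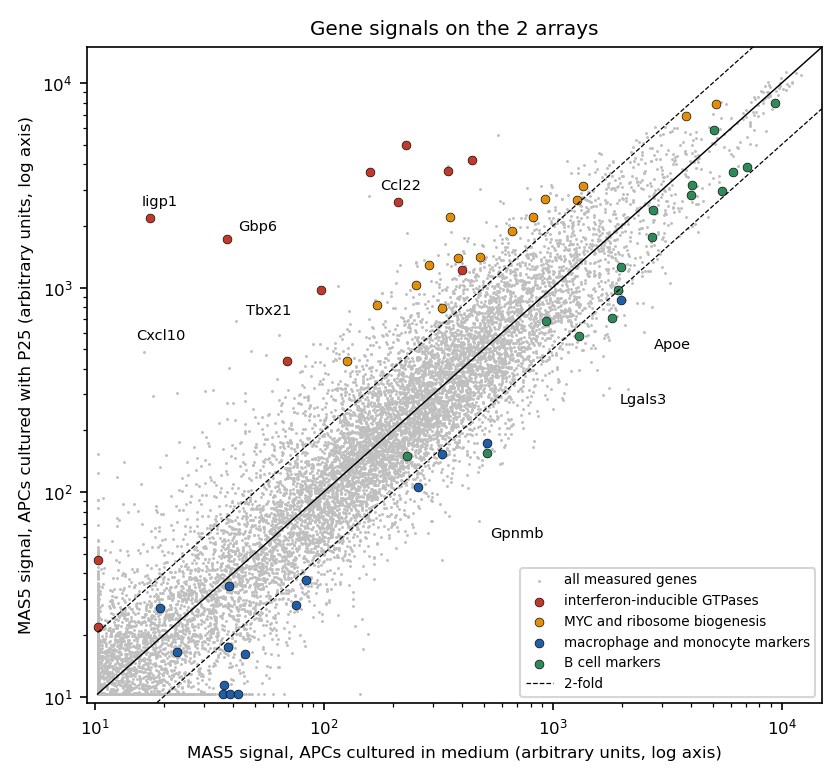
MAS5 signal of each measured gene on the medium array (horizontal, log axis, arbitrary units) against the P25 array (vertical, log axis, arbitrary units); the solid line marks equal signal, the dashed lines a 2-fold difference, and values below the floor of 10.3 are drawn at the floor. All 12 interferon-inducible GTPases lie above the upper dashed line, 13 of 15 MYC and ribosome biogenesis genes do so too, and 12 of 15 macrophage and monocyte markers lie below the lower one.

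Iigp1, Gbp6, Cxcl10, Igtp and Gbp2, all interferon-inducible, had the largest ratios among genes above the floor on both arrays. All 12 measured interferon-γ-inducible GTPases, which act in defence of cells against intracellular pathogens, were at least 2-fold higher with P25, with a median of 10.3-fold. Iigp1 had a signal of 2183.5 against 17.5, or 124.7-fold, where the medium signal lay below its array's median of 18.4. Gbp6 was 45.3-fold and Gbp2 21.8-fold higher, Igtp had a signal of 3657 against 159, and the lowest of the genes above the floor on both arrays was Gbp3 at 3.03-fold. The second probe sets of Iigp1 and Gbp6 gave log2 ratios of 6.07 and 5.66. Of 22 other measured interferon-γ response genes, 13 were at least 2-fold higher and none was at least 2-fold lower, with a median of 2.65-fold. Cxcl10, a chemokine that attracts activated T cells, was 29.2-fold higher (482 against 16.5), Socs1, a feedback inhibitor of cytokine receptor signalling, 16.4-fold, and Irf1, a transcription factor of the interferon response, 6.32-fold. Acod1, whose enzyme makes itaconate, was above the floor with P25 alone, at least 12.02-fold higher. Jak2 and Ciita, the master regulator of MHC class II genes, had the lowest log2 ratios of this list, -0.60 and -0.70. Genes usually assigned to type I interferon were higher as well. Of 25 measured, 20 were at least 2-fold higher, all 25 had a log2 ratio above 0, and the median was 3.19-fold. Oasl2 and Ifit3 led the list at 10.5-fold and 9.24-fold, and Oas1a (1.68-fold) and Isg20 (1.67-fold) came last. Each of these 3 list medians lay above those of all 10000 random lists of equal size and matched signal (percentile 100). On the same arrays the macrophage and monocyte markers were lower with P25, with a median log2 ratio of -1.28. The sizes of the largest ratios depended on the floor, which is low for such signals: with a floor at the 60th percentile the log2 ratio went from 6.96 to 5.82 for Iigp1, from 4.87 to 3.64 for Cxcl10, from 4.04 to 2.93 for Socs1 and from 3.59 to 1.68 for Acod1. The type I list's median log2 ratio was 1.68 on the main floor and 0.96 with a floor at the 75th percentile, a setting chosen after the data were seen.

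**Figure D2:**
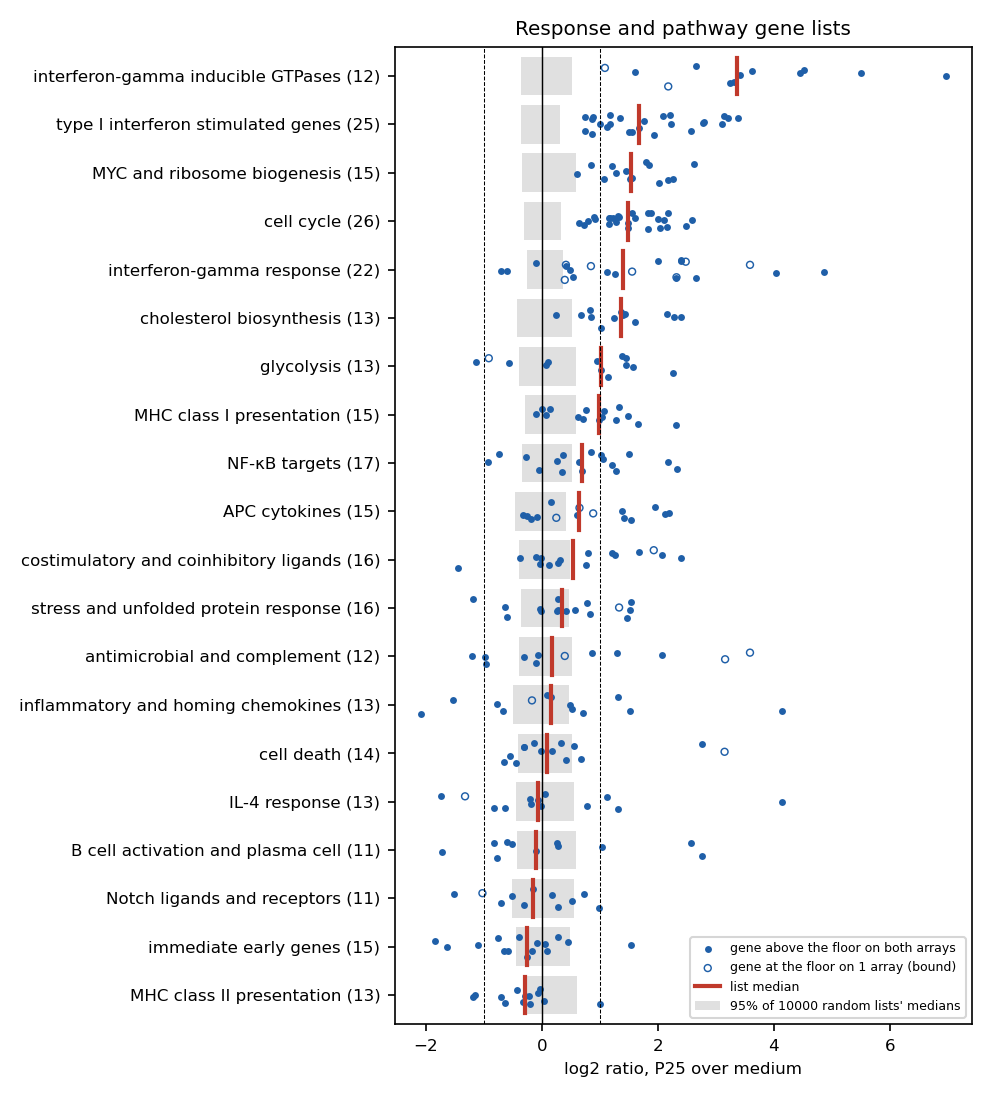
Log2 ratio of P25 over medium (horizontal axis) for every measured member of the 20 response and pathway gene lists fixed beforehand; filled points are genes above the floor on both arrays, open points are bounds with 1 array at the floor, red bars are list medians, and grey bands hold 95% of the medians of 10000 random lists matched in size and signal. The interferon, MYC, cell cycle and cholesterol lists lie to the right of their bands, from a median of 3.36 for the GTPases to 1.36 for cholesterol biosynthesis, and the MHC class II list lies at the left edge of its band (-0.29).

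Of 15 measured genes of MHC class I presentation 7 were at least 2-fold higher with P25 and 8 were within 2-fold, with a median of 1.98-fold (percentile 100). The higher ones included Nlrc5 (4.97-fold), the transactivator of class I genes, the immunoproteasome subunits Psmb9 (3.14-fold) and Psmb10 (2.42-fold), and the peptide transporter subunit Tap1 (2.79-fold, with a log2 ratio of 0.44 on its other probe set). The brightest probe sets of the heavy chain genes H2-K1 and H2-D1 had log2 ratios of 0.08 and 0.00, while other probe sets of the same genes reached 1.81 and 1.59. None of 13 MHC class II genes was at least 2-fold higher and 2 were at least 2-fold lower, with a median log2 ratio of -0.29 (percentile 2.76). Ifi30 was just under the threshold at 1.9994-fold higher, and passed it with median and spike-in scaling (log2 ratios of 1.14 and 1.15). The lowest were H2-Ob, which restrains class II peptide loading, at 2.29-fold lower, and Marchf1, a ubiquitin ligase that removes class II from the cell surface, at 2.22-fold lower. The class II chains H2-Aa, H2-Ab1 and H2-Eb1 were within 2-fold on their brightest probe sets, at log2 ratios of -0.29, -0.43 and -0.20. Their signals were 4795 or more on both arrays, and whether probe sets this bright still follow a change was not tested, so these values cannot rule one out. Other probe sets of H2-Aa reached 0.24, and the second one of H2-DMa had 0.86 against -0.22 on the brighter. B cell markers were lower on the same arrays, with a median log2 ratio of -0.65.

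Of 16 measured costimulatory and coinhibitory ligands, 6 were at least 2-fold higher and 1 lower, with a median of 1.45-fold (log2 ratio 0.54, percentile 98.6). Over the 15 above the floor on both arrays, without Cd70, the median log2 ratio was 0.31, inside the band of random lists (-0.39 to 0.48). Icam1 was 5.25-fold, Tnfsf9 (the ligand of 4-1BB) 4.23-fold and Cd40 3.18-fold higher, and Cd70 was at least 3.81-fold higher. The coinhibitory ligand Cd274 was 2.39-fold higher, while Vsir was 2.72-fold lower, with a log2 ratio of -0.21 on its other probe set. Cd80 and Cd86 were 1.21-fold and 1.73-fold higher, within 2-fold, but Cd80 was dim (36.9 against 30.4). Among 15 measured APC cytokines, 6 were at least 2-fold higher and none lower, with a median of 1.57-fold (percentile 99.8). Tnf was 4.58-fold (85.1 against 18.6), Il6 4.34-fold and Ebi3 3.86-fold higher. The IL-12 subunits Il12a and Il12b were within 2-fold, at log2 ratios of -0.18 and -0.25. Il12b was dim (30.4 against 36.3), with a log2 ratio of -0.93 on its other probe set, so a change in it cannot be ruled out. With the 60th percentile floor Tnfsf9 came to a log2 ratio of 1.40, Tnf to 1.14, Il6 to 0.86 and Cd70 to 0.02, the last 2 under 2-fold. Most of these cytokine probe sets were dim. With the 75th percentile floor only Ebi3, Il12a and Tgfb1 were measured, and the list's median log2 ratio went from 0.65 to -0.18, the value of Il12a. The 13 measured chemokines went both ways, 3 at least 2-fold higher and 2 lower, with a median of 1.12-fold (percentile 77.5). Ccl22, a ligand of CCR4, was 17.7-fold higher (2804 against 158), Cxcl2 2.87-fold higher, and Ccl5 4.24-fold and Ccl9 2.88-fold lower. With the 60th percentile floor Cxcl2 came to 0.49. With the 75th percentile floor only Ccl22, Ccl6, Ccl9 and Ccl5 were measured, and the list's median log2 ratio went from 0.16 to -0.77.

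Genes of growth and division were higher with P25. All 26 measured cell cycle genes had a log2 ratio above 0 and 21 were at least 2-fold higher, with a median of 2.81-fold. They covered the entry into S phase (Ccne2 6.02-fold, E2f1 5.61-fold), DNA replication (Mcm3 4.11-fold, Rrm2 4.29-fold) and mitosis (Cdk1 4.46-fold), with Bub1b (1.66-fold) and Ccnb2 (1.56-fold) lowest. The probe sets of E2f1 ran from 0.09 to 2.49 in log2 ratio and those of Bub1b from -0.87 to 0.87. Of 15 MYC and ribosome biogenesis genes 13 were at least 2-fold higher, with a median of 2.90-fold. Srm, which makes spermidine, was 6.19-fold and Myc itself 4.78-fold higher (820 against 172), and Ncl (1.80-fold) and Npm1 (1.53-fold) were the exceptions. Of 13 cholesterol biosynthesis genes 9 were at least 2-fold higher, with a median of 2.57-fold, led by Fdps (5.25-fold) and Idi1 (4.86-fold). These 3 medians had percentile 100. Of 13 glycolysis genes 7 were at least 2-fold higher, with a median of 2.03-fold (percentile 99.98). Hexokinase Hk2 was 4.79-fold and Ldha 2.96-fold higher, whereas the glucose transporter Slc2a3 was 2.19-fold lower on its brightest probe set (-0.05 on another) and Slc16a3, a lactate exporter, was above the floor with medium alone, at least 1.89-fold lower. Nme1, a nucleoside diphosphate kinase outside these lists, was 11.3-fold higher on its brightest probe set, with a log2 ratio of 1.81 on the other. Macrophage, neutrophil and B cell markers were lower on the same arrays, as given with the marker lists.

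Of 17 NF-κB targets 7 were at least 2-fold higher and none lower, with a median of 1.61-fold (percentile 99.6). The survival gene Bcl2l1 was 5.01-fold and Marcksl1 4.50-fold higher, while Fscn1 and Ccr7 had the lowest log2 ratios, -0.75 and -0.93. The remaining response lists had medians inside the range of 95% of the random lists, though single members stood out. In the antimicrobial and complement list (12 measured, 4 at least 2-fold higher, 1 lower, median 1.12-fold, percentile 68.6), complement factor B, Cfb, was at least 8.93-fold higher (log2 ratio 1.25 with the 60th percentile floor) and the lysozyme gene Lyz2 was 2.29-fold lower. In the cell death list (14 measured, 2 at least 2-fold higher, none lower, median 1.06-fold, percentile 58.6), the necroptosis effector Mlkl was at least 8.87-fold (1.24 with that floor) and the death receptor Fas 6.81-fold higher, and the lowest log2 ratios were those of Bbc3 (-0.55) and Bcl2l11 (-0.65). The stress and unfolded protein response list had 4 of 16 genes at least 2-fold higher and 1 lower, with a median of 1.27-fold (percentile 92.6). Asparagine synthetase Asns was 2.90-fold and the chaperone Hsph1 2.86-fold higher, and Hmox1 was 2.27-fold lower. Among 15 immediate early genes 1 was at least 2-fold higher and 3 lower, with a median log2 ratio of -0.26 (percentile 11.8). Jun was 2.91-fold higher, and Fos (3.10-fold), the phosphatase gene Dusp1 (3.59-fold) and Zfp36 (2.13-fold) were lower. The 11 Notch ligands, receptors and targets had none at least 2-fold higher and 2 lower, with a median log2 ratio of -0.16 (percentile 25.9). Dtx1 was 2.87-fold lower and Jag1 at least 2.03-fold lower (-0.09 on its other probe set, and under 2-fold with median and spike-in scaling). The ligands Dll1 and Dll4 had log2 ratios of 0.18 and 0.52, both from dim probe sets (38.4 against 33.9 and 19.9 against 13.9). Of 13 IL-4 response genes 3 were at least 2-fold higher and 2 lower, with a median log2 ratio of -0.06 (percentile 34.0) that came to 0.08 with median scaling and 0.09 with spike-in scaling. Its higher members included Ccl22 and Ccl17 (2.49-fold), and its lower ones were Retnla (3.34-fold, but a log2 ratio of -0.05 with the 60th percentile floor) and Mrc1 (at least 2.504-fold).

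**Figure D3:**
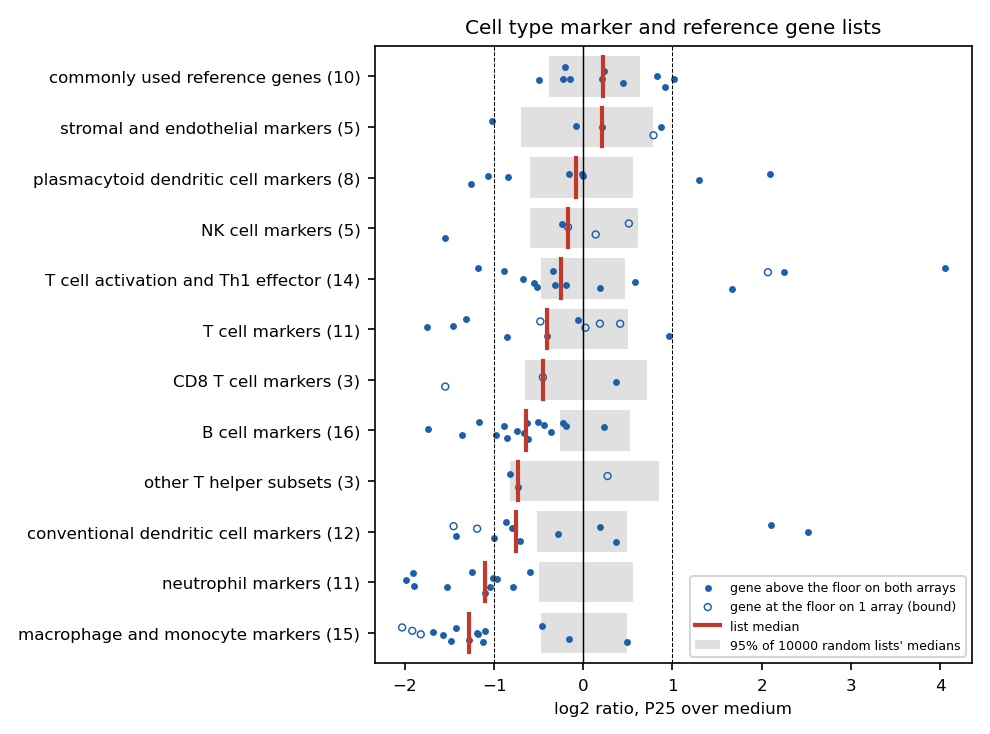
Log2 ratio of P25 over medium (horizontal axis) for every measured member of 11 cell type marker and activation lists and of the commonly used reference genes, with the same symbols, median bars and bands of random lists as in the plot of response lists; erythroid markers, with 2 measured genes, are left out. The macrophage (-1.28), neutrophil (-1.10), conventional dendritic cell (-0.75) and B cell (-0.65) medians lie left of their bands.

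Markers of several APC and myeloid cell types were lower with P25. Of 15 macrophage and monocyte markers 12 were at least 2-fold lower and none higher, with a median of 2.44-fold lower (percentile 0). The lowest were Ccr2 (at least 4.09-fold lower) and the complement gene C1qb (at least 3.78-fold lower), Csf1r was 2.96-fold lower, and Cd14 and Fcgr1 had the highest log2 ratios, -0.16 and 0.49. With the 60th percentile floor Ccr2 and C1qb came to -0.12 and -0.01, and the list's median to -1.10. All 11 neutrophil markers had a log2 ratio below 0 and 8 were at least 2-fold lower, with a median of 2.14-fold lower (percentile 0). Mpo was 3.96-fold and Mmp8 3.75-fold lower, and S100a8 1.52-fold lower. Mpo went from a log2 ratio of -1.98 to -1.03 with the 60th percentile floor. Of 16 B cell markers 15 had a log2 ratio below 0 and 3 were at least 2-fold lower, with a median of 1.57-fold lower (percentile 0.01). Vpreb3 was 3.35-fold and the kinase gene Blk 2.57-fold lower, whereas Ms4a1, which encodes CD20, had a log2 ratio of 0.23 that came to -0.01 after loess. Of 12 conventional dendritic cell markers 4 were at least 2-fold lower and 2 higher, with a median of 1.68-fold lower (log2 ratio -0.75, percentile 0.19). Over the 10 of them above the floor on both arrays the median log2 ratio was -0.50, inside the band of random lists (-0.51 to 0.49), so the list stood apart only with its bounded members. Cadm1 (at least 2.74-fold) and Sirpa (2.69-fold) were lowest, each under 2-fold by the median over its probe sets (-0.85 and -0.76), while the transcription factor gene Zbtb46 was 5.72-fold and the endocytic receptor gene Ly75 4.32-fold higher. With the 60th percentile floor the log2 ratio of Zbtb46 went from 2.52 to 1.05, and its probe sets ran from 1.36 to 2.52. The B cell activation and plasma cell list went both ways, with 3 of 11 genes at least 2-fold higher and 1 lower and a median log2 ratio of -0.10 (percentile 24.5), which came to 0.04 and 0.05 with median and spike-in scaling. Fas and the early activation marker Cd69 (5.95-fold) were higher, and the plasma cell marker Sdc1 was 3.32-fold lower. Of 8 plasmacytoid dendritic cell markers 2 were at least 2-fold higher and 2 lower, with a median log2 ratio of -0.08 (percentile 43.8) that came to 0.06 and 0.07 with the same scalings. Bst2, also an interferon-stimulated gene, was 4.26-fold higher and Ccr9 2.40-fold lower, though -0.31 by the median over its probe sets. Klk1 was 2.45-fold higher on its brightest probe set, and its probe sets ran from -0.61 to 1.29 in log2 ratio.

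T cell markers were few and, apart from Cd2, dim. Of 16 named on the array, 5 were below the floor on both arrays, among them Cd3e, Cd3d and Cd4. Of the 11 measured, 3 were at least 2-fold lower and none higher, with a median log2 ratio of -0.40 (percentile 3.08). Cd2 was 3.36-fold and Il7r 2.74-fold lower, and Cd3g had the highest ratio at 1.95-fold higher (21.6 against 11.1). Cd2 was far brighter (339 against 1140) than Cd3e, Cd3d and Cd4, so its signal cannot be assigned to T cells. In the list of T cell activation and T helper 1 genes, 8 of 22 were below the floor on both arrays, among them the cytokine genes Ifng and Il2. Of the 14 measured, 4 were at least 2-fold higher and 1 lower, with a median log2 ratio of -0.26 (percentile 15.2) that came to 0.00 with median scaling and turned to 0.26 without a floor. Tbx21, which encodes the T helper 1 transcription factor T-bet, was 16.6-fold higher (687 against 41.3), and the interleukin-2 receptor gene Il2ra 4.76-fold higher (log2 ratio 1.66 with the 60th percentile floor). Lta was 3.19-fold and Gzmb at least 4.20-fold higher, and Tnfrsf9 was 2.27-fold lower, but with the 60th percentile floor Gzmb came to 0.16 and Tnfrsf9 to -0.26. Il12rb1, a subunit of the interleukin-12 receptor outside this list, was above the floor with P25 alone, at least 14.9-fold higher (log2 ratio 1.99 with that floor). Other lymphocyte markers gave little signal. The 3 measured genes of other T helper subsets, Foxp3, Ikzf2 and Maf, were within 2-fold (median log2 ratio -0.73, percentile 3.62). Of 5 measured NK cell markers 1, Klrd1, was 2.94-fold lower (median -0.17, percentile 25.3) and came to -0.99 with that floor. Of 3 measured CD8 T cell markers 1, Cd7, was at least 2.93-fold lower (median -0.45, percentile 7.33). Of 2 measured erythroid markers, Hemgn was at least 4.53-fold higher (0.27 with that floor) and Slc4a1 had a log2 ratio of 0.02 (median 1.10). Of 5 stromal and endothelial markers 1, Pecam1, was 2.03-fold lower (median 0.21, percentile 65.6). The 10 measured reference genes had a median log2 ratio of 0.22 (percentile 69.6), and 1, Pgk1, also in the glycolysis list, was 2.03-fold higher.

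Beyond these lists, Ffar2, a receptor for short-chain fatty acids, was 13.4-fold higher, with a log2 ratio of 3.75 that went to 2.99 with the 60th and 1.33 with the 75th percentile floor. The chemokine-binding receptor gene Ackr3 was at least 6.67-fold and Ptgs2, which encodes cyclooxygenase-2, at least 5.69-fold higher, although a second probe set of Ptgs2 had a log2 ratio of -0.04. With the 60th percentile floor Ackr3 and Ptgs2 came to 0.83 and 0.60, under 2-fold. The lower genes included Tbxa2r, the thromboxane receptor (8.69-fold), S100a4 (7.06-fold), Gpnmb (6.65-fold), Cyp4f18 (5.59-fold) and Lgals3, which encodes galectin-3 (5.44-fold, 324 against 1765). Fabp4, a fatty acid binding protein of macrophages and fat cells, was above the floor with medium alone, at least 14.0-fold lower. With the 60th percentile floor Tbxa2r came to -1.94 and Fabp4 to -1.90. Tbc1d4 was 7.71-fold lower on its brightest probe set, while its other measured probe set had a log2 ratio of 0.52. The linker histone gene H1f2 was 6.69-fold lower, with log2 ratios from -2.74 to -0.52 over its 3 probe sets. Ccl17, Jag1, Mrc1, Cadm1 and Cd7 were below the 60th percentile floor on both arrays. Among genes given above as within 2-fold, so were Il12b, Cd80, Dll1, Dll4, Cd14 and Fcgr1, and their small ratios cannot rule out a change. With the 75th percentile floor, added after the data were seen, genes dim on 1 or both arrays lost much of their ratio. Tbx21 went from a log2 ratio of 4.05 to 2.49, and Ccne2 (0.90), E2f1 (0.52), Asns (0.49), Lta (0.37), Ly75 (0.92), Klk1 (0.07), Il12rb1 (0.33) and Acod1 (0.02) came under 2-fold among the higher genes. Among the lower genes Ccl9 (-0.88), Mmp8 (-0.92), Sirpa (-0.59), Tbxa2r (-0.28), Tbc1d4 (-0.35) and Fabp4 (-0.24) did so. Marchf1, Tap1, Csf1r, Zfp36, Pgk1, Slc2a3, Hmox1, Pecam1, Ccl17, Mrc1 and Vsir came under 2-fold under at least 1 other alternative. With 1 array per condition, none of these differences has a replicate check.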

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

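The list medians and the median, quantile and loess scalings were planned, while their use against the explanations below, the limit to signals of at least 100, the difference of the macrophage and neutrophil medians and the spike-in scaling were chosen after the results were seen. Among the 4827 measured probe sets without a gene name, 589 were at least 2-fold lower with P25 and 205 at least 2-fold higher. Named probe sets of like signal would give 377.5 lower and 384.5 higher. Among 680 measured probe sets with several gene names, 75 were at least 2-fold higher and 55 lower, against 70.1 and 44.8 from named ones of like signal. These probe sets enter no comparison above, and no explanation was tested for them.

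Tbx21, Il2ra, Lta and Gzmb were at least 2-fold higher with P25, although the cells had been enriched for APCs after the culture. With the 60th percentile floor Gzmb came to 0.1617. With the 75th percentile floor Lta came to 0.3724, Il2ra and Gzmb were not measured, and Tbx21 alone stayed past 2-fold, at 2.4922. More T cell RNA in the P25 sample would raise T cell markers. Their median log2 ratio was -0.4030 over 11 measured genes and -0.86 over the 7 above the floor on both arrays. With the 60th percentile floor it was -1.1405, where only Cd2, Cd28 and Il7r were measured. Only 1 marker, Cd2, had a mean signal of at least 100, and 4 lay above 0 (Cd3g, and Trat1, Bcl11b and Thy1 as bounds). Cd2 read 339 against 1140 where Cd3e, Cd3d and Cd4 were below the floor on both arrays. Its signal can therefore not be assigned to T cells, and its fall is no measure of them. Dim markers that went both ways leave more T cell RNA open. Activation of a small number of T cells left in both samples cannot be told apart from expression in the APCs either, since the T cell activation list had a median of -0.2555 with 4 genes at least 2-fold higher and 8 genes below the floor. Expression of these genes by the P25-cultured APCs themselves stays open and was not tested.

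Macrophage and neutrophil markers were lower together. Scaling of the arrays would shift all genes together. The scalings tried moved the median log2 ratio of all genes from 0.02 to at most 0.16. They could therefore not bring these medians near 0, and the higher of both was -0.9471 under the least favourable scaling. Set against genes of the same arrays, both medians lay below those of all 10000 matched random lists (percentile 0). Noise of dim probe sets would spare bright members, but the 11 members with a mean signal of at least 100 had a median of -1.1971 and 9 of them were at least 2-fold lower. A smaller share of macrophages and neutrophils in the P25 sample may account for the pattern, but was not tested. That 25 of 26 markers were below 0 is the pattern itself. The list medians differed by -0.1861 (macrophage minus neutrophil), while members within a list were uneven. Neutrophil markers ran from -0.60 (S100a8) to -1.98 (Mpo), and macrophage markers from 0.49 (Fcgr1, dim) to -2.03 (Ccr2, a bound). A smaller share cannot be told apart from lower expression per cell, since mixed RNA carries no cell numbers.

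Cell cycle genes were higher with P25, as were those of ribosome biogenesis. A trend of the ratio with signal would be taken out by loess, and the cell cycle median after loess was 1.4186. Dividing T cells carried into the P25 sample would bring T cell markers with them. The 11 measured markers had a median of -0.4030, but nearly all were dim and they went both ways, so dividing T cells cannot be excluded. Division of APCs, B cells among them, in response to P25 and T cells stays open as a hypothesis, and a sorted sample would be needed to test it.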

How the results depend on the processing

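No paired analysis was possible because each condition has 1 array. Of 343 list medians under alternatives 331 moved by less than the probe set spread of 0.58, as did 1495 of 1619 values of named genes, and 15 of 26 counts stayed within 1.5 times. That spread is of single genes and is wide for a list median, so small medians could change sign within it. The T cell activation median went from -0.26 to 0.26 without a floor and was counted as unmoved. Many of these comparisons could not have moved by 0.58. Median and spike-in scaling shift ratios above the floor by one constant well under it, and a changed floor leaves genes brighter than it as they were. The counts of unmoved values are therefore no measure of robustness. The counts followed the floor by construction, since it sets which dim genes enter. With a floor at the 25th percentile 1983 genes were at least 2-fold higher and 1507 lower, without floor 3245 and 2593, and at the 60th percentile the lower count was 591. At the 75th percentile, a floor added after the data were seen, 657 were higher and 357 lower. Thresholds of 1.5-fold and 4-fold gave 2701 and 2354, and 176 and 51. The higher count stayed within 1.5 times under median and spike-in scaling, and so did the lower count. Among list medians, the interferon-γ response came to 2.0384 with the 25th percentile floor and 2.3141 without floor, and other T helper subsets to 0.2174 and 0.2693, a change of sign that rests on 3 dim genes in the main setting. CD8 T cell markers came to -1.6821 with the 25th percentile floor, -1.4930 without floor and -1.1278 with a pseudocount, and NK cell markers to 0.6383 without floor. T cell markers came to -1.1405 with the 60th percentile floor, where only Cd2, Cd28 and Il7r were measured. With the 75th percentile floor type I interferon genes came to 0.9585, APC cytokines to -0.1796 and chemokines to -0.7739. The cytokine and chemokine medians there cover only the few members still measured. Klk1 reversed, to -0.2610 with the median over probe sets and -0.6019 without _x_at and _s_at probe sets, since its probe sets disagree. The cause of the other moves was not tested. The GTPase median ranged from 3.27 to 3.66, cell cycle from 1.16 to 1.64, and macrophage markers from -1.31 to -1.09. Of the 101 named genes past 2-fold, 17 came under it with the 60th percentile floor, Rgs13 (-0.79) among them, and 16 with the 75th. Further ones were not measured with these floors and are not in those counts. With the 75th they included Tnf, Il6, Tnfsf9, Il2ra, Zbtb46, Cfb, Mlkl, Ptgs2, Ackr3, Ccr2, C1qb and Mpo, so 16 understates the calls lost there. Lists with under 3 measured genes under a setting were not compared there. Signal over background limits dim genes, whose probe sets disagreed more (SD 0.68 under a signal of 100, 0.46 at 100 or more). The share of genes past 2-fold was 16.1% under a signal of 100 (463 higher and 499 lower of 5983). At 100 or more it was 17.1% (753 and 432 of 6914). The floor shrinks the ratios of dim genes, so these like shares do not show that dim genes are measured as well. Higher genes outnumbered lower ones at 100 or more, but not under 100.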

Other observations

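The 6 gene lists in this part were chosen after the data were seen, so their counts describe these arrays and are no independent evidence. Of 17 genes of serine, one-carbon and nucleotide synthesis 14 were at least 2-fold higher, with a median of 2.75-fold, and all 17 had a log2 ratio above 0. Shmt1 was 8.35-fold, Psat1 5.26-fold and Mthfd2 3.93-fold higher. Of 19 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, 10 were at least 2-fold higher and all had a log2 ratio above 0, with a median of 2.01-fold. Wars, also an interferon-γ response gene, led them at 5.27-fold, followed by Iars (2.498-fold). Proteasome subunits other than those of the immunoproteasome had a median of 1.96-fold, with 8 of 19 at least 2-fold higher and none lower. All 3 medians lay above those of 10000 matched random lists (percentile 100).

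Genes of macrophage lipid handling and lysosomes were lower with P25, with 11 of 18 at least 2-fold lower, none higher and a median of 2.40-fold lower (percentile 0). Apoe was 4.13-fold lower (606 against 2502), Lpl 3.63-fold and Abca1 2.89-fold, while Cd36 was 1.61-fold higher. The macrophage and monocyte markers were lower by a like amount on these arrays (median log2 ratio -1.28, against -1.26 here). Genes that place lymphocytes within tissue or let them leave it were lower too, 11 of 17 at least 2-fold, with a median of 2.41-fold lower (percentile 0). They included the transcription factor gene Klf2 (3.39-fold), the sphingosine-1-phosphate receptor gene S1pr1 (2.87-fold), Cxcr4 (3.93-fold) and, at least 6.501-fold lower, Rgs13, whereas the B cell follicle receptor gene Cxcr5 had a log2 ratio of 0.29. With a floor at the 60th percentile Rgs13 came to -0.79, under 2-fold. On the same arrays the B cell markers were lower (median log2 ratio -0.65), while the T cell markers had a median of -0.40 and went both ways. Cytokine receptors went both ways, 3 of 20 at least 2-fold higher and 4 lower, with a median log2 ratio of -0.35 (percentile 2.58). Il12rb1, Il2ra and Cd40 were the higher ones, and the interferon-γ receptor genes Ifngr1 and Ifngr2 were within 2-fold, at -0.42 and -0.80, although the second probe set of Ifngr2 had 0.61.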
